A study of Homo sapiens with 4 samples.

How the data were processed

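RNA was measured in 4 libraries of A673 cells, 1 for each of 2 siRNAs (control or against FAT4) at 24 h and 48 h after transfection with RNAiMAX, per the labels' protocols. Total RNA was taken up in TRIzol and made into strand-specific mRNA libraries, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, TopHat2, SAMtools, HTSeq and the human build hg19, without an order or settings. The deposited values were whole-number counts of reads per gene, not normalized, and each of the authors' files held 1 library. The gene annotation, the counting mode, the strand setting and the siRNA sequences are not given in the sources used here. Counts of overlapping or antisense genes and of genes with near-identical copies (such as RPS29 and SLC7A5, which have pseudogenes, and TMEM189, which has a read-through neighbour) are therefore uncertain.

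Each file ended in 5 counter entries that name no gene, and these stayed out of library sizes and tests. Reads outside genes were 19.48% of assignable reads in control 24 h, 20.21% in control 48 h, 19.6% in FAT4 siRNA 24 h and 20.54% in FAT4 siRNA 48 h. Reads that fell on more than 1 gene were 0.772% to 0.804%. Alignments that were not unique numbered 43.14 to 44.63 per 100 uniquely placed reads. Gene counts totalled 22625833, 19614913, 15196813 and 15413960 in that order of libraries, and the 10 most abundant genes held 3.07% to 3.78% of them. Pearson correlations of log2 CPM between libraries lay between 0.9593 and 0.9829.

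From the counts, edgeR 4.0.16 in R 4.3.3 was run with TMM scaling (factors 0.9727 to 1.026). Genes were filtered by filterByExpr on the 4 groups with a minimum count of 10 and total of 15, which kept 13712. A quasi-likelihood fit held siRNA and time as additive terms over all 4 libraries, and each term was tested, two-sided, with Benjamini-Hochberg adjustment at 0.05. This fit leaves 1 residual degree of freedom, and its prior degrees of freedom were infinite, so all genes shared 1 dispersion trend (common biological coefficient of variation 0.0737). The p-values weigh the mean change over both times, or over both siRNAs, in single libraries, and say nothing of the spread between cultures. A gene with a strong change at a single time can still be called, as GDF15 was. Beside the test, log2 ratios of TMM-scaled CPM plus 1 were taken at each time, which understate the changes of genes of low abundance. Exact 95% Clopper-Pearson intervals belong to the plain CPM ratios with nothing added. These intervals and the floor of 3 counts per library cover counting error only. Ratios were counted among 10595 genes with a mean of at least 5 CPM.

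Gene lists, 45 with 1175 entries, were fixed from general knowledge together with the tests, the alternatives and the rule for named genes before the data were examined, and 1155 entries matched a gene in the files. Lists with at least 5 tested members, 41 of them, were tested with camera in limma 3.58.1 at a preset correlation of 0.01. They were tested again with an estimated correlation and with fry. Both of these rest on the 1 residual degree of freedom of the fit, so hardly any list could pass them. Member counts are given over all genes tested and adjusted over the list alone. At each time a list's median log2 ratio was placed among 10000 random lists of equal size matched on mean expression in 20 bins. The random lists were not matched on GC content, with which the siRNA ratios moved.

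Named genes were FAT4, then the 12 higher and 12 lower genes with the largest smaller absolute log2 ratio of both times among genes with a mean of at least 5 CPM and 1 sign. To these came the 4 highest and 4 lowest at each time, the 6 higher and 6 lower of the time comparison by the same rule, and up to 4 members per list. The genes with the largest differences between the times, the words, and GDF15, DDIT3 and TRIB3 as members of the ATF4 list were chosen after their values were seen. Some genes that the rule picks are not reported here.

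Transcript sequences of GENCODE release 29 were used only for transcript length, GC content and 3' UTRs. A transcript was matched for 94% of tested genes. The release is on another build than hg19, so no coordinates are given. A correction for GC content and length used natural splines with 5 and 4 degrees of freedom per library as offsets in the edgeR fit. Words of 7 bases were searched in UTRs of at least 50 bases in 9956 genes, and 15317 words were scored for a shift in log2 ratio.

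The count fit was tested on simulated data with 200 genes changed, for the siRNA comparison over both times. With 1 dispersion for all genes, edgeR recovered 73% of genes changed 1.5-fold and 92% of those changed 2-fold, and 6.25% of calls among 13564 genes were false. With dispersions that differed between genes, it recovered 31% and 86%, and 18.2% of calls among 13573 genes were false. Both simulations set dispersions around 0.005, near the common dispersion of 0.00543 estimated from these libraries. No spread between cultures was measured or added, so these shares of false calls need not hold for the real calls. A planted gene list of 35 members was called, and among the 41 lists tested 0 of those that share no member with it were called. Genes were drawn independently of each other, so this does not measure false list calls where genes move together. A planted GC trend gave 5778 calls without the offset and 0 with it among 12766 genes. A planted word was recovered as the leading word, and without a word effect the largest absolute score among 9956 genes was 3.95.

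Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, robust empirical Bayes, models with 1 factor, other pseudocounts (0.25 and 5 CPM) and other CPM floors (1 and 20). Files were read and figures drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.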

Results

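Gene counts were measured by RNA-seq in A673 cells, an Ewing sarcoma line that carries the EWSR1-FLI1 fusion. The cells had been transfected with a control siRNA or with an siRNA against FAT4, and RNA was taken 24 h or 48 h later. FAT4 encodes an atypical cadherin of the Fat and Dachsous family, which is tied to planar cell polarity and to the Hippo pathway. The series held 1 library for each siRNA and time, so no value below has a replicate culture behind it. Counts assigned to genes summed to 22625833 in control 24 h, 19614913 in control 48 h, 15196813 in FAT4 siRNA 24 h and 15413960 in FAT4 siRNA 48 h. A floor of 3 counts stood for 0.133 to 0.197 CPM (counts scaled to a common library size). Of 23228 genes in the files, 5735 had 0 counts in all 4 libraries and 13712 were tested.

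The targeted transcript was lower with the FAT4 siRNA at both times. FAT4 counts were 3678 in control 24 h, 2992 in control 48 h, 1061 in FAT4 siRNA 24 h and 941 in FAT4 siRNA 48 h. These counts were 165, 149, 71.8 and 60.2 CPM. The ratio of FAT4 siRNA to control was 0.436 at 24 h, with a 95% counting interval of 0.407 to 0.467, and 0.405 at 48 h, with an interval of 0.376 to 0.436. In the edgeR fit over both times FAT4 fell by 1.25 on the log2 scale (SE 0.0978, adjusted p = 8.65e-34, lower in both pairs of libraries).

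The comparison of the siRNAs over both times asked which transcripts differed between the FAT4 siRNA and the control siRNA on average over 24 h and 48 h. The matricellular genes CTGF and CYR61, both known YAP and TAZ targets, rose together with the phospholipid-binding protein ANXA1. The adiponectin receptor ADIPOR1, the large neutral amino acid transporter SLC7A5 and the interferon-induced gene IFI6 fell. Interferon response genes and sterol synthesis genes were lower as groups, and genes of mitosis, of the YAP and TAZ program and of the set that EWSR1-FLI1 represses were higher as groups. These group calls were made with a preset correlation between genes, and each had adjusted p = 0.798 with an estimated correlation. The latter test rests on the 1 residual degree of freedom of the fit and could hardly call any list. Its values here and below therefore do not show whether correlation between genes accounts for a call. Most single changes were small, with a median absolute log2 fold change of 0.456 among the genes called.

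CTGF rose by 1.93 on the log2 scale (SE 0.140, adjusted p = 3.50e-39), from 14.6 to 41.4 CPM at 24 h and from 7.26 to 39.3 CPM at 48 h. ANXA1 rose by 1.08 (SE 0.0891, adjusted p = 2.77e-30), from 463 to 1015 CPM at 24 h and from 402 to 819 CPM at 48 h. The interleukin 6 receptor IL6R rose by 1.60, the TWEAK receptor TNFRSF12A by 1.40, and the deubiquitinase OTUD6B by 1.26. Further genes among the 12 higher ones rose by 1.04 to 1.25. They were TTPAL, TMEM189, the RNA polymerase III subunit POLR3G, the Golgi transport protein GOLT1B, the lysosomal membrane protein LAMP2, and the cullin 3 adaptor SPOPL.

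ADIPOR1 fell by 1.41 (SE 0.0987, adjusted p = 1.23e-41), from 153 to 54.5 CPM at 24 h and from 161 to 64.1 CPM at 48 h. SLC7A5 fell by 1.19 (SE 0.0894, adjusted p = 1.26e-36), from 1277 to 567 CPM at 24 h and from 1355 to 587 CPM at 48 h. The secreted Wnt antagonist FRZB fell by 1.64, the keratan sulfate sulfotransferase CHST1 by 1.53, and the class II phosphoinositide 3-kinase PIK3C2B by 1.40. IFI6 fell by 1.30 (SE 0.165, adjusted p = 3.55e-13). The neuronal carnitine palmitoyltransferase CPT1C fell by 1.48, the prohormone convertase inhibitor PCSK1N by 1.59, MCF2L by 1.43, the synaptotagmin SYT11 by 1.22 and the microtubule-associated gene FSD1 by 1.67. With FAT4, these completed the 12 lower genes, each lower in both pairs of libraries.

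**Figure D1:**
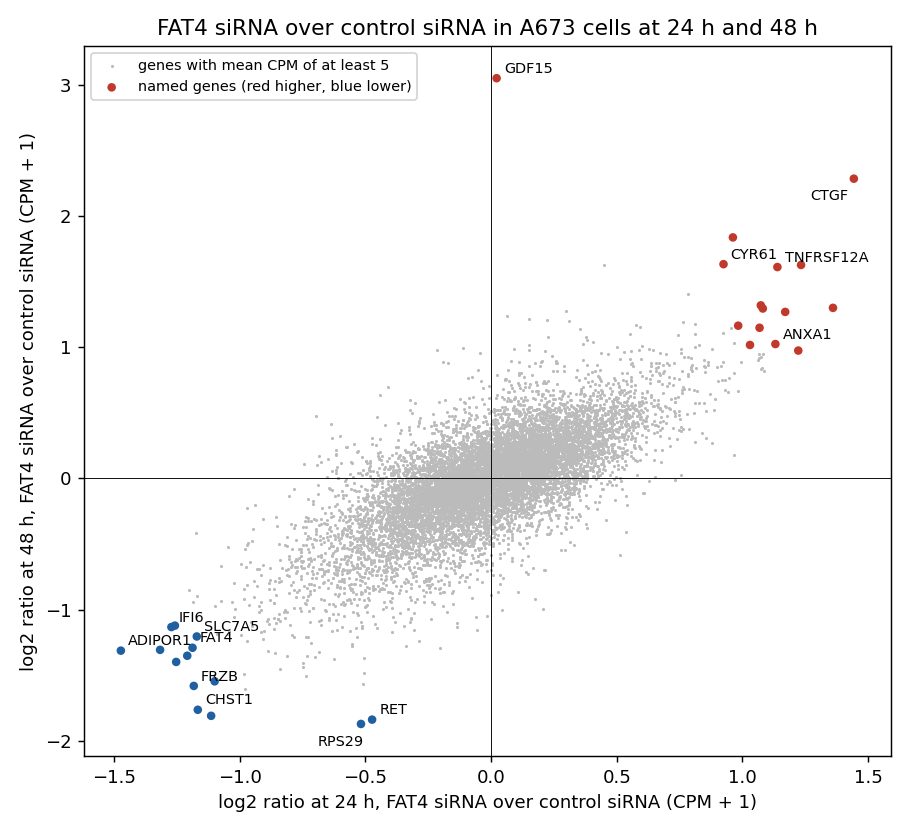
Log2 ratio of FAT4 siRNA to control siRNA at 24 h (horizontal axis) and at 48 h (vertical axis), computed on CPM plus 1, for the 10595 genes with a mean of at least 5 CPM. Grey points are genes, red and blue points are named higher and lower genes, each ratio rests on 1 library per siRNA, and the values correlated across genes at r = 0.717.

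The edgeR quasi-likelihood test called 3555 of the 13712 genes at an adjusted p under 0.05, 1625 higher and 1930 lower. Of these, 83 higher and 226 lower genes changed at least 2-fold and 2427 changed less than 1.5-fold. The ratio had the same sign at both times for 3533 called genes and opposite signs for 22. The counting intervals excluded 1 in the same direction at both times for 3166 called genes. DESeq2 called 1234 genes, all of them among the 3555, and a model without the time term called 0 at the adjusted threshold and 1706 at an unadjusted p under 0.05. The fit over both times favoured genes whose signs agree, and no replicate culture measured how they would vary between experiments.

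The siRNA ratio moved with base composition. Across genes, the Spearman correlation of the log2 ratio with transcript GC content was -0.576 at 24 h and -0.233 at 48 h, where genes are not independent replicates. At 24 h the median log2 ratio was 0.193 in the genes of lowest GC content and -0.236 in those of highest GC content, with the genes split at the quartiles. At 48 h these medians were 0.0869 and -0.0995. Of 3459 genes called among those with a matched transcript, 61.8% were also called after correction for GC content and length, when 2633 genes were called.

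The ratio also moved with short words in the 3' UTR. Genes whose annotated 3' UTR held the 7-base word TTGGACT were lower at both times. Its score, a test statistic across 9956 genes, was -13.5 at 24 h and -10.1 at 48 h, and it ranked first at both times among words marking lower genes. Genes with the word AGCCTTA were higher, with scores of 9.83 and 9.06, and that word ranked first at both times on that side. The largest absolute score of any word in the comparisons between times was 4.42. TTGGACT or the overlapping TGGACTA occurred in 14.6% of the genes searched. Among the 69 searched genes that were called and at least 2-fold lower, 25 (36.2%) held one. AGCCTTA or its overlapping forms occurred in 24.7% of the genes searched, and in 15 (51.7%) of the 29 searched genes called at least 2-fold higher. The words were picked by these same ratios, so the shares are no separate support. Of the 12 named higher genes, 7 carried such a form, among them ANXA1 and GOLT1B, whereas CTGF, IL6R and LAMP2 did not. The UTRs of FAT4, FRZB and PIK3C2B held a form of TTGGACT, and those of ADIPOR1, SLC7A5 and IFI6 did not.

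Among gene lists fixed from textbook knowledge, the interferon response moved the furthest. Of 35 members tested, 22 fell and 0 rose, and the same counts came out when adjusted over the list alone. IFI6 fell by 1.30, IFIT1 by 1.26, IFI44L by 1.05 and the ISG15 protease USP18 by 0.94. The median log2 fold change was -0.54 (camera adjusted p = 9.78e-09), against adjusted p = 0.798 with an estimated correlation and a range of 8.79e-10 to 0.798 over the alternatives. The median log2 ratio was -0.57 at 24 h and -0.43 at 48 h, each at percentile 0 of 10000 random lists matched on expression. Median transcript GC content of the list was 49.8%, and with the GC and length correction 21 members fell.

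Sterol synthesis genes and targets of SREBP2 were lower at both times. Of 25 members, 15 fell and 1 rose, and adjusted over the list alone the counts were also 15 and 1. TM7SF2 fell by 0.80 and DHCR7 by 0.68, and both encode reductases late in cholesterol synthesis. HMGCS1, the cytosolic HMG-CoA synthase, fell by 0.39 and the mevalonate decarboxylase MVD by 0.56. The median was -0.26 (camera adjusted p = 0.00361), against adjusted p = 0.798 with an estimated correlation and a range of 0.000281 to 0.798 over the alternatives. With the GC and length correction, 11 members fell and 2 rose, and the median was -0.17. In the list of fatty acid synthesis genes, 5 of 14 fell and 0 rose, with 7 lower when adjusted over the list alone, and the list missed the threshold (camera adjusted p = 0.0536). With the correction 3 of these 14 fell. FASN fell by 0.39, ACSS2 by 0.41 and FADS2 by 0.30 in that list.

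Target genes of YAP and TAZ, the effectors of the Hippo pathway, were higher. Of 23 members, 8 rose and 1 fell, as they did when adjusted over the list alone. Beside CTGF, CYR61 rose by 1.31 (SE 0.118, adjusted p = 2.16e-25), the ectonucleotidase NT5E by 1.0 and the angiomotin-like gene AMOTL2 by 0.56. The median was 0.21 (camera adjusted p = 0.000293), against adjusted p = 0.798 with an estimated correlation and a range of 3.39e-05 to 0.798 over the alternatives. The list median lay at percentile 99.8 of matched random lists at 24 h and 82.7 at 48 h. Hippo pathway components did not move as a group, with 2 of 23 higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.772). Their median was slightly negative (-0.0122) while their mean (0.000746) and the direction of the test were positive. With the GC and length correction the direction of that test turned negative, with 5 members higher and 3 lower. TEAD1, a transcription factor partner of YAP, rose by 0.70, FRMD6 rose by 0.48 and the upstream regulator NF2 fell by 0.46.

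The list of Fat and Dachsous cadherins and planar cell polarity genes was not called. Of 21 members, 4 including FAT4 fell and 1 rose, the same as adjusted over the list alone, and the median was -0.17 (camera adjusted p = 0.0799). VANGL2 fell by 0.43 and ROR2 by 0.48, but neither was called by DESeq2 or after the GC and length correction. FZD6 had a log2 fold change of -0.31 and did not pass the test. The median GC content of this list was 56.8%, and with the GC and length correction its median turned positive, at 0.03, with 3 members higher and 3 lower. Classical cadherins and junction genes were not called either, with 2 of 19 higher and 6 lower, 2 and 8 adjusted over the list alone (camera adjusted p = 0.413). The median log2 ratio of this junction list was 0.10 at 24 h and -0.26 at 48 h, at percentiles 90.2 and 0.45 of matched random lists. The catenins CTNND1 and JUP fell by 0.88 and 0.63 in that list.

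Genes that the EWSR1-FLI1 fusion is known to repress were higher. Of 31 members, 14 rose and 2 fell, or 15 and 4 adjusted over the list alone, with a median of 0.24 (camera adjusted p = 2.31e-05). That call had adjusted p = 0.798 with an estimated correlation and a range of 1.26e-06 to 0.798 over the alternatives. CTGF, CYR61, NT5E and IGFBP3 were in both this list and that of YAP and TAZ targets. Genes that the fusion activates went both ways, with 7 of 45 higher and 16 lower, or 9 and 17 adjusted over the list alone (camera adjusted p = 0.167). The transcription factor NKX2-2 fell by 0.85, LBH by 0.66, LINGO1 by 0.68 and MAPT by 0.87.

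Genes of G2 and mitosis were slightly higher. Of 49 members, 17 rose and 0 fell, or 19 and 0 adjusted over the list alone. HMMR rose by 0.92, the cyclin CCNA2 by 0.41, the kinetochore gene NDC80 by 0.40 and CENPF by 0.34. The median was 0.19 (camera adjusted p = 2.75e-06), against adjusted p = 0.798 with an estimated correlation and a range of 6.87e-06 to 0.798 over the alternatives. Their median transcript GC content was 42.3%, and with the GC and length correction the median was 0.13, with 11 members higher and 1 lower. Genes of S phase were not called, with 13 of 46 higher and 7 lower, also when adjusted over the list alone (camera adjusted p = 0.153).

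Mesenchymal and matrix genes passed narrowly and held members of both directions. The list shared COL1A1, COL1A2, COL3A1, COL6A1, COL6A2, FN1, TNC, THBS1, LOX, TIMP3 and VIM with the genes that EWSR1-FLI1 represses. The calls of these lists were therefore not independent of each other. Of 41, 13 rose and 4 fell, or 14 and 6 adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.0493). The call had adjusted p = 0.798 with an estimated correlation and a range of 0.000433 to 0.798 over the alternatives. With the GC and length correction the median was 0.29, with 18 members higher and 3 lower. The laminin chain LAMC1 rose by 0.70 and the collagen COL3A1 by 0.57, whereas the lysyl oxidase LOXL1 fell by 0.77 and COL18A1 by 1.16. Nuclear retained and structural RNAs, which vary with RNA quality and library preparation, moved as well: 4 of 8 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.0552). NEAT1 rose by 0.45, MALAT1 by 0.29, SNHG1 by 0.31 and GAS5 by 0.25. This list was called among genes of at least 5 CPM and after the GC and length correction, when 1 of the 7 members with a matched transcript rose, but not with an estimated correlation (adjusted p = 0.798, without the correction).

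**Figure D2:**
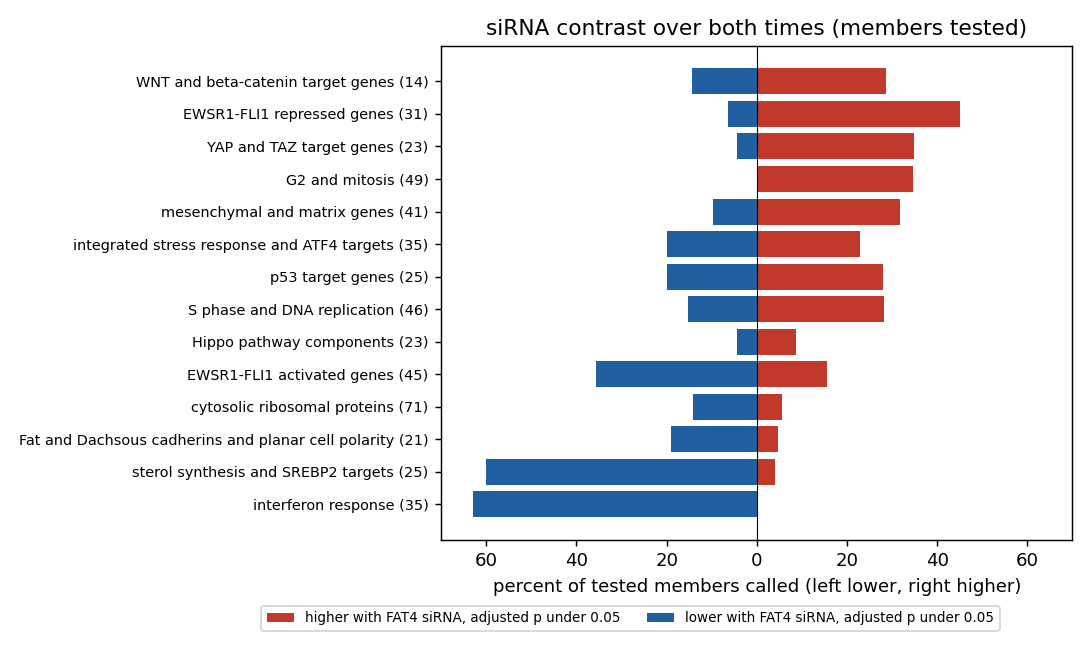
Percent of tested members called in the edgeR fit over both times for the 6 lists called by camera and 8 lists not called, with the number of members in brackets. Bars to the right are members higher with the FAT4 siRNA and bars to the left are members lower, such as the 22 of 35 interferon response genes.

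At each time alone, 1 library per siRNA was compared, so only ratios are given. Among the 10595 genes with a mean of at least 5 CPM, 19 were at least 2-fold higher and 27 at least 2-fold lower at 24 h. At 48 h the numbers were 42 and 115. All 46 genes at 24 h and all 157 at 48 h had the same sign at the other time, and 26 were at least 2-fold apart at both. The ratios at 24 h and 48 h correlated across genes at Pearson r = 0.717 and a Spearman correlation of 0.689, and 75.3% of genes had the same sign. Among the highest ratios at 24 h were those of CTGF (log2 1.44), IL6R (1.23) and SPOPL (1.22), and the lowest those of ADIPOR1 (-1.47), CPT1C (-1.32), IFI6 (-1.27) and SYT11 (-1.26).

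At 48 h the stress cytokine GDF15 stood apart, with 31.2 CPM in FAT4 siRNA against 2.88 CPM in control, a log2 ratio of 3.05. At 24 h GDF15 was at 0.880 and 0.851 CPM, a log2 ratio of 0.02. CTGF followed at 2.29, the orphan receptor MRGPRF at 1.84 and CYR61 at 1.63. The receptor tyrosine kinase RET was at 29.03 CPM against 106 CPM in control at 48 h (log2 ratio -1.84) and at 81.6 against 114 CPM at 24 h (-0.47). The ribosomal protein gene RPS29 had a log2 ratio of -1.87 at 48 h and -0.52 at 24 h, and its many near-identical copies make its counts uncertain. FSD1 and CHST1 followed at -1.81 and -1.76. GDF15, RET and RPS29 were called over both times by edgeR but not by DESeq2.

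**Figure D3:**
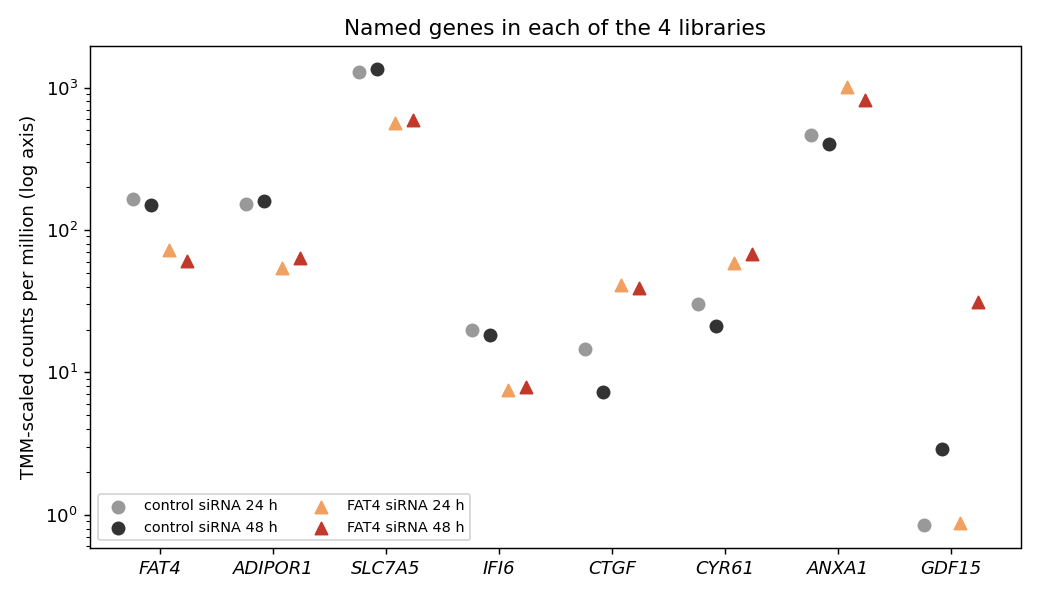
CPM per library for named genes, with each point 1 library (control siRNA or FAT4 siRNA at 24 h or 48 h). FAT4 is at 165, 149, 71.8 and 60.2 CPM, and GDF15 is at 31.2 CPM in FAT4 siRNA 48 h and at no more than 2.88 CPM in the other libraries.

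The siRNA ratio differed between the times by at least 1 on the log2 scale for 22 genes, 12 with a higher ratio at 48 h and 10 with a lower one. The hedgehog effector GLI1 had log2 ratios of -0.22 at 24 h and 0.98 at 48 h. IL20RB had 0.06 and 1.24, FAM171A2 had -0.70 and 0.48, and the transporter ABCA5 had 0.21 and -0.99. LOC150381 had -0.05 and -1.16. These differences could not be tested, because a model with 1 library per siRNA and time leaves no residual. GLI1 was in the list of hedgehog targets and in that of genes that EWSR1-FLI1 activates. The hedgehog list was not called, with 2 of 8 members higher and 2 lower, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.406). The median log2 ratio of the hedgehog list was -0.26 at 24 h and -0.32 at 48 h.

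The comparison of 48 h with 24 h, over both siRNAs, asked what changed with time in culture after transfection. Targets of ATF4, hypoxia genes and genes of lipid synthesis were higher at 48 h, and MYC targets and S phase genes were lower. Each of these group calls, made with a preset correlation, had adjusted p = 0.714 with an estimated correlation. As between the siRNAs, the latter test had too few residual degrees of freedom to decide. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, rose by 3.09 (SE 0.116, adjusted p = 1.09e-149), from 14.96 to 127 CPM with the control siRNA and from 14.6 to 124 CPM with the FAT4 siRNA. The aldolase ALDOC rose by 3.19, the mitochondrial folate enzyme ALDH1L2 by 2.69, the lipoprotein receptor VLDLR by 2.90, the cholesterol exporter ABCG1 by 3.64 and the lactate exporter SLC16A3 by 4.29. The muscle protein gene NEB fell by 2.49, the ubiquitin ligase MARCH4 by 2.46, the metallothionein MT1G by 2.07 and the neurotensin receptor NTSR1 by 1.61. SAMD11 fell by 1.45 and METTL7B by 1.31.

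Over both siRNAs 3646 genes were called, 1892 higher and 1754 lower at 48 h, and 454 of the higher and 93 of the lower were at least 2-fold apart. Higher genes were 51.9% of the calls, against 66.3% when the libraries were scaled by their totals and 65.2% by upper quartiles. DESeq2 called 1176, all among the 3646, and a model without the siRNA term called 50. With the control siRNA alone, 92 genes were at least 2-fold higher and 29 lower at 48 h, and with the FAT4 siRNA 154 and 33. The time ratios of the 2 siRNAs correlated across genes at Pearson r = 0.741 and a Spearman correlation of 0.664. The Spearman correlation of the time ratio with transcript GC content was -0.297 with the control siRNA and 0.00674 with the FAT4 siRNA.

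Targets of ATF4 and the integrated stress response, which respond to amino acid shortage, rose almost throughout. Of 35, 32 rose and 1 fell, or 33 and 1 adjusted over the list alone, with a median of 1.04 (camera adjusted p = 2.32e-47, adjusted p = 0.714 with an estimated correlation). Of 25 hypoxia genes, 17 rose and 0 fell, or 18 and 0 adjusted over the list alone, with a median of 0.76 (camera adjusted p = 1.52e-17, adjusted p = 0.714 with an estimated correlation). DDIT4 rose by 2.74, the carbonic anhydrase CA9 by 4.76, STC2 by 1.90 and the pyruvate dehydrogenase kinase PDK1 by 1.99. DDIT4 and STC2 were also in the list of ATF4 targets. Of 25 sterol genes, 20 rose and 0 fell, or 21 and 0 adjusted over the list alone (median 0.53, camera adjusted p = 4.94e-17, adjusted p = 0.714 with an estimated correlation). INSIG1 rose by 1.53 and HMGCS1 by 1.15. Fatty acid synthesis genes rose in 10 of 14 cases, also when adjusted over the list alone, with ACSS2 higher by 1.51 and SCD by 0.95 (camera adjusted p = 3.78e-10, adjusted p = 0.714 with an estimated correlation).

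Other lists went either way between the times. Of 32 MYC target genes, 25 fell and 0 rose, or 26 and 0 adjusted over the list alone, with a median of -0.38 (camera adjusted p = 2.75e-15, adjusted p = 0.714 with an estimated correlation). The ribosome assembly genes UTP20 and BOP1 fell by 0.85 and 0.80. Of 46 S phase genes, 24 fell and 0 rose, or 27 and 0 adjusted over the list alone (camera adjusted p = 1.64e-09, adjusted p = 0.714 with an estimated correlation). The cyclin CCNE1 fell by 0.91, without a call by DESeq2, and the helicase subunit MCM5 by 0.53. Cytosolic ribosomal protein genes fell in 20 of 71 cases with 0 higher, also when adjusted over the list alone (median -0.18, camera adjusted p = 4.98e-08, adjusted p = 0.714 with an estimated correlation). Of 35 interferon response genes, 13 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.000398, adjusted p = 0.714 with an estimated correlation), with IFIT1 lower by 0.99. The BMP targets ID3 and ID1 fell by 1.13 and 1.06 in a list of 16 with 8 lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 0.0016, adjusted p = 0.714 with an estimated correlation). Genes of G2 and mitosis were not called between the times, with 2 of 49 higher and 6 lower, also when adjusted over the list alone (median -0.05, camera adjusted p = 0.161). IGF and PI3K pathway genes were called higher, with 8 of 21 higher and 3 lower, also when adjusted over the list alone (median 0.18, camera adjusted p = 0.015, adjusted p = 0.714 with an estimated correlation). NF-kB and inflammatory genes were called higher too (median 0.92, camera adjusted p = 0.000252, adjusted p = 0.714 with an estimated correlation). Heat shock genes (camera adjusted p = 0.00013), cytoskeleton and SRF targets (0.000248), genes that EWSR1-FLI1 activates (0.0021), YAP and TAZ targets (0.015) and RNA interference machinery (0.0312) were called lower, and none of these 5 with an estimated correlation. For genes that EWSR1-FLI1 activates, the median time log2 ratio was 3.2e-05 with the control siRNA and -0.265 with the FAT4 siRNA. These lay at percentiles 83.6 and 0 of matched random lists. For YAP and TAZ targets the medians lay at percentiles 39.1 and 35.4.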

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

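The test of leading words in UTRs and the question of the innate response were chosen only after the results were seen, as were the GC and length correction, the thinning of libraries and the medians of members without a word. For the list medians, a bound of 0.75 of the uncorrected median was set first, and the looser bound of 0.5 used here was chosen after the intervals were seen. The intervals in this section are 95% bootstrap intervals over genes or list members. Genes are not independent replicates, so these intervals cover no spread between libraries or cultures.

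Many genes, 3555 in all, were called between the siRNAs over both times. Unequal depth did not account for this, since thinning all libraries to the smallest kept 91.1% of the number of calls (interval 89.9 to 92.2) and 3160 of the same genes. GC content and length as the whole cause were also argued against, since the correction gave 76.1% of the number of calls (interval 74.1 to 78.2), although only 61.8% of the calls were the same genes. The siRNAs may have acted on transcripts through short matches in UTRs, since TTGGACT had a score of -13.5 at 24 h against at most 4.42 for any word between times. Whether such matches were the whole cause could not be decided. Of the genes without a word of either kind, 28.2% were called. However, a UTR with only another form, such as TGGACTT (score -9.54 at 24 h), counted as without a word. Changes passed on from matched genes would be counted there too. Loss of FAT4 stays open as an untested explanation.

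Interferon response genes were lower with the FAT4 siRNA at both times. With the GC and length correction the list median was 0.857 of that without it (interval 0.727 to 1.22) and 21 members fell, which argues against this bias as the main cause by the bound of 0.5 but not by that of 0.75. Of the 35 members tested, 25 were searched for words, and 5 of these held TTGGACT or TGGACTA. Members without either word had a median 1.01 times that of all 25 searched (interval 0.783 to 1.3). This argues against TTGGACT and TGGACTA in the searched members' own UTRs as the main cause. Members with only another form, such as TGGACTT, counted as without a word, so matches to other forms stay open. Matches in other genes that act on the members were outside that test and stay open. An unequal innate response to the transfected RNAs may explain the pattern as well as loss of FAT4 might. With 0 untransfected libraries these cannot be told apart, and which siRNA moved the genes is open.

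Target genes of YAP and TAZ were higher with the FAT4 siRNA. The list median with the GC and length correction was 1.11 times that without it (interval 0.673 to 5.28), and 10 members rose against 8, which argues against this bias by the bound of 0.5 but not by that of 0.75. Members without an AGCCTTA-type word had a median 0.48 times that of the 20 searched, with an interval of -4.13 to 2.86. The median thus left open whether matches to such words, possibly of the control siRNA, moved the list. The siRNA sequences were not given, so no word could be assigned to an siRNA. Loss of FAT4 and other causes were not tested. Of the 15 members without the word, 6 rose and 1 fell. CTGF carried neither type of word and CYR61 carried the AGCCTTA type, so a hypothesis of a raised YAP and TAZ program rests in part on genes that matches could reach.

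Genes whose siRNA ratio had opposite directions at the 2 times were picked out by that contrast, and the differences between times were not tested. The log2 ratio at 48 h minus that at 24 h was -1.20 for ABCA5, -0.32 for ACTG1 and 1.18 for FAM171A2. It was 0.51 for ID3, 0.70 for NOTCH3, 0.25 for RRP12, 0.51 for TXNIP and 0.30 for XBP1. Reads outside genes, which no comparison used, were 19.6% in FAT4 siRNA 24 h against 19.48% in control, and 20.54% in FAT4 siRNA 48 h against 20.21% in control.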

How the results depend on the processing

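The GC and length correction, the thinning and the demand on counting intervals were chosen only after the results were seen. No called result reversed, but among lists that were not called the GC and length correction turned the median or the direction of the test for Fat and Dachsous genes, Hippo components, NOTCH targets and the unfolded protein response, among others. Of the alternatives for the main counts, 72 planned and 13 added ones stayed within 1.5 times or kept the call, and 33 planned and 1 added one moved. The cause was not tested unless stated.

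DESeq2 called 1234 genes between the siRNAs (599 higher, 635 lower) and 1176 between the times (531 higher, 645 lower), all among the edgeR calls. Without the other factor, 0 genes (0 higher, 0 lower) were called between the siRNAs, against 1706 at an unadjusted p under 0.05 with edgeR, and 50 between the times (46 higher, 4 lower), since that factor then entered the residual.

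Counts of 2-fold ratios moved by construction with the pseudocount and the CPM floor. At 24 h, 73 genes passed with 0.25 CPM added, 16 with 5 CPM and 25 above 20 CPM. At 48 h, 61 passed with 5 CPM added and 77 above 20 CPM. Between times in control, 64 passed with 5 CPM added, 184 above 1 CPM and 60 above 20 CPM, and with the FAT4 siRNA 97, 318 and 80. Differences between times of at least 1 numbered 37 with 0.25 CPM added, 5 with 5 CPM, 66 above 1 CPM and 8 above 20 CPM. The correlation of both times was 0.667 above 1 CPM, 0.744 above 20 CPM, 0.728 with 5 CPM added and 0.689 by Spearman.

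Of the 6 lists called, 0 were called with an estimated correlation and 0 with fry. With 1 residual degree of freedom neither test could be expected to call a list, so these losses decide nothing. The GC and length correction called 12, namely these 6 and, all higher, MYC targets (adjusted p = 0.00302), immediate early genes (0.0282), targets of WNT (0.0412), of TGF-beta and BMP (0.0412) and of SRF (0.0413), and nuclear retained RNA (0.0282), which the same test called without the correction too (0.0354). That test without the correction did not call mesenchymal and matrix genes (0.0535). None of the 6 lists gained was called with an estimated correlation, which was tried without the correction only. Among named genes, DESeq2 lost 9 of 53 siRNA results and 14 of 72 time results, and the correction lost VANGL2 and ROR2 and gained FZD6. No scaling moved the median of all genes by more than 0.058. Thinning gave 3238 calls. Leaving out 1 library leaves no residual in the fit. Depth limits genes near 0.133 to 0.197 CPM.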

Other observations

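The GC and length correction was chosen only after the results were seen, as was the grouping of the lists below into paragraphs.

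Several gene groups outside the report had members that changed strongly while the group was not called. In RNA interference machinery, 4 of 13 members fell and 1 rose, or 4 and 2 adjusted over the list alone. TNRC6C fell by 0.94, TARBP2 by 0.81, DICER1 by 0.49 and the Argonaute gene EIF2C1 by 0.37, although the list median was 0.03, its mean -0.13 and its direction down (camera adjusted p = 0.406). Among apoptosis regulators, 7 of 21 rose and 4 fell, or 8 and 6 adjusted over the list alone (camera adjusted p = 0.372). The death effectors BAK1 and BAD fell by 1.19 and 0.80 and the survival gene BCL2 rose by 0.87. In the unfolded protein response, 5 of 20 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.925, median 0.00653, mean -0.00057, direction up), with the chaperone CALR lower by 0.73 and its membrane-bound relative CANX higher by 0.81. The direction of that test turned down with the GC and length correction. Of 36 autophagy and lysosome genes, 6 rose and 6 fell, or 7 and 6 adjusted over the list alone, with LAMP1 higher by 0.81 and WIPI2 lower by 0.49 (camera adjusted p = 0.406). Of 35 ATF4 targets, 8 rose and 7 fell, or 10 and 7 adjusted over the list alone (camera adjusted p = 0.485). GDF15, which DESeq2 did not call, was higher by 2.77, DDIT3 by 0.68 and TRIB3 by 0.51, and SLC7A5 was lower by 1.19, CEBPB by 0.82 and CBS by 0.64.

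Further lists, of signalling and other groups, were not called between the siRNAs without the correction. Of 12 NOTCH targets, 4 fell and 0 rose, the same adjusted over the list alone, with HEYL lower by 1.56 (camera adjusted p = 0.308). With the GC and length correction 1 NOTCH target rose and 1 fell, and the list median turned from -0.04 to 0.04. Immediate early genes rose in 5 of 23 cases and fell in 2, the same adjusted over the list alone, with JUN higher by 0.89 and EGR1 by 0.83 and BTG2 lower by 0.73 (camera adjusted p = 0.193). That list was called higher after the GC and length correction, with a median of 0.27 against 0.15, but not with an estimated correlation (adjusted p = 0.837, without the correction). Its median log2 ratio was -0.15 at 24 h and 0.24 at 48 h, at percentiles 9.16 and 99.6 of matched random lists. Those random lists were not matched on GC content, and the median transcript GC content of the immediate early genes was 55.4%. Of 16 MAPK feedback genes, 5 rose and 3 fell, or 7 and 4 adjusted over the list alone, with PHLDA1 higher by 0.64 and ETV5 lower by 0.82 (camera adjusted p = 0.406). Of 25 p53 targets, 7 rose and 5 fell, or 7 and 6 adjusted over the list alone, with CDKN1A higher by 0.49 and SESN1 lower by 0.64 (camera adjusted p = 0.466). Of 25 hypoxia genes, 4 rose and 5 fell, or 4 and 6 adjusted over the list alone, with BNIP3L higher by 0.51, AK4 lower by 1.10 and MXI1 by 0.89 (camera adjusted p = 0.463). With the correction, 1 hypoxia gene rose and 2 fell. Of 21 neuronal genes, 2 rose and 5 fell, the same adjusted over the list alone, with NGFR lower by 0.79 and TUBB3 by 0.74 (camera adjusted p = 0.193), against 3 and 3 with the correction. Of 71 cytosolic ribosomal protein genes, 4 rose and 10 fell, the same adjusted over the list alone (camera adjusted p = 0.308). Of markers of other cell types, 1 blood, 4 epithelial and 4 endothelial genes passed the filter, and of these KRT8 alone was called, lower by 0.52. Of 9 fibroblast and muscle markers tested, 2 fell and 0 rose, the same adjusted over the list alone, with THY1 lower by 0.61 and PDGFRB by 0.47 (median -0.25, camera adjusted p = 0.406). With the correction 1 of these 9 rose and 2 fell.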
